A study of Canis lupus familiaris with 15 samples.

How the data were processed

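RNA from 15 samples of 5 dogs was labelled with Cy3 and hybridised to a canine Agilent array, 1 sample per array on 4 slides read on 2 scan days. Per the labels' protocols, tissue or needle aspirates were the source and only RNA of good integrity was labelled with the Low Input Quick Amp kit. Per the file headers, the authors extracted spot intensities with Agilent Feature Extraction 11.0.1.1, whose protocol subtracts the local background and corrects spatial trends within each array. These processed intensities are not normalised between arrays. The deposited series table holds spot median intensity minus local background median in linear scale. This was checked against the scanner values, and 678300 of 678300 cells were equal within 0.01. Other deposited columns, per the file headers, hold flags of 0 or 1 per spot for signal well above background, saturation and non-uniform or outlying pixels. No column with a mean spot signal was among them.

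Each array had 43803 spots that were not controls, for 43603 probes. Between 2 and 50 spots per array marked as outlying were left out, and 0 were saturated. The 75th percentile of the processed signal ran from 367 in the remission aspirate to 1241 in the Jake biopsy. The number of arrays limits the precision.

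The processed signal was put on the log2 scale and the 75th percentile of the array was subtracted. Spots of 1 probe were averaged. Probes were named only through the RefSeq identifiers of the array, which gave symbols to 2186 of 43603 probes (5.01%), or 1357 symbols. Other probes, among them 19130 that carry Ensembl transcript identifiers, kept the identifier as their name. This gave 36604 targets, and for a target with several probes the probe with the highest mean was used. A target was tested when it was well above background on every array of at least 1 of the groups compared. The reference assembly differs from the one used to place the array grid, so no genome positions were attached.

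Groups were taken from the labels. The tested comparisons were resistant biopsies (4) against skin (2), the sensitive biopsy (1) against resistant biopsies (4), the remission aspirate (1) against the other aspirates of Rosco (5), relapse aspirates (3) against the earlier aspirates of Rosco (2), and the post-mortem sample (1) against relapse aspirates (3). A group of 1 array borrows its spread from the other group. Differences were tested with limma 3.58.1 (linear model and moderated statistic) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all targets tested and a threshold of 0.05. The error given beside a difference is the standard error of that model. No comparison had 3 or more samples in both groups, so labels were not permuted. A fold is written as "at least" where a gene was not well above background on any array of the dimmer group. It compares the mean of the brighter group with the mean, over the arrays of the dimmer group, of the higher of the probe's own signal and the lowest signal among probes well above background on that array.

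Gene lists were tested with camera of limma at a preset correlation of 0.01 between genes, and again with the correlation estimated from the arrays. A list needed 5 tested genes. Of 30 lists fixed before the data were examined 17 had at least 5 named genes and were tested. Another 4 lists (exocrine gland epithelium, T cell activation, proliferation and chemokines) were put together after the gene names and some values had been seen, and their p-values were adjusted together with the fixed ones. None of the calls made at the preset correlation held with an estimated correlation. That version takes its degrees of freedom from the residuals of each fit, only 2 to 4 here, so few lists could pass. For proliferation after death the estimated correlation was −0.009, below the preset, yet the camera p went from 3.88e-06 to 0.0384. A lost call is therefore not by itself a sign of correlation between genes. Pairs of single arrays were compared without a test, over targets well above background on both arrays, while focus genes are given also when dim. A 2-fold minimum was used for counts, and each list's median was placed among those of 10000 random lists matched in 20 bins of expression (seed 11).

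The comparisons, the fixed lists, the threshold, the filter, the alternatives and the rule for named genes were chosen before the data were examined. The rule took, for each tested comparison, the 10 higher and 10 lower named genes with the largest difference among those past the threshold whose groups do not overlap. It also took 2 members of each list called by camera and a set of 18 focus genes, of which only ABCB1, ABCC1, MS4A1 and BCL6 were among the named genes. A few genes that the rule took are not reported here. For pairs it took the focus genes and the 5 higher and 5 lower named genes. BIRC5, CDC25A, UBE2S and TYMS, the only named members of lists that could not be tested, were added after the gene names were known. CA6, KLK1, TFF3, LTB, CD38 and the values of single arrays were picked after the data had been seen.

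Alternatives for each comparison were quantile normalisation, normexp background correction (offset 50) of the spot medians followed by quantile normalisation, the deposited series table with a floor at 0.01 of the 75th percentile, no filter on dim probes, a filter on every array, the mean of all probes of a gene, 1 fit of all 15 arrays, a trended and robust spread, slide or dog as a block, and leaving out each array in turn. Fits within 1 slide, fits with each array in turn as the lone one, and the added lists were chosen after seeing the data. The analysis was tested on simulated data with 50 targets planted at each of 2, 4, 8 and 16-fold. For biopsies against skin 0, 0, 11 and 30 were recovered, for relapse against earlier aspirates 0, 6, 38 and 45, and for post-mortem against relapse 1, 28, 49 and 50, with 4, 7 and 15 false calls. For both other comparisons 0 were recovered at any fold, with 1 false call for the sensitive biopsy and 0 for remission. A list of 20 targets planted at 2-fold was called in all 5 comparisons and 0 of 20 unchanged lists were. The noise was drawn independently for each target, so genes of these lists were uncorrelated, while estimated correlations in the tested lists reached 0.978. The result therefore does not show how camera at the preset correlation treats correlated lists. The simulated spreads were already shrunk toward a common value, which can overstate the recovery of single targets. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 read the files and drew the figures.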

Results

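RNA from 15 canine samples was hybridised to 1-colour Agilent arrays, 1 array per sample. The samples came from 5 dogs with lymphoma, called MalcolmX, Jake, Rosco, Dog Y and Thai in the labels. There were 2 skin biopsies (MalcolmX and Rosco), 4 biopsies of drug-resistant tumours (MalcolmX, Jake, Rosco and Dog Y) and 1 biopsy of a drug-sensitive tumour (Thai). The labels describe the biopsies of Rosco and Dog Y both as taken before treatment and as drug resistant, and the title of the Thai sample calls it naive. MalcolmX also gave 1 needle aspirate of the tumour after metformin, a diabetes drug that lowers glucose output by the liver. Rosco gave 7 further samples: 1 aspirate after failed chemotherapy and before metformin, 1 aspirate in remission after metformin, 3 relapse aspirates after metformin, 1 aspirate labelled a second drug-resistant tumour, and 1 tumour sample taken after death. The titles of the 3 relapse samples call them no remission, while their source names call them relapse. Values are log2 signals relative to the 75th percentile of the same array, so that 0 is a bright probe. The lowest signal well above background ran from −9.05 to −5.98 over the arrays, so the level close to background differs between them. Between 66.8% and 75.9% of the 43603 probes were well above background on an array. The number of arrays limits the precision, and the 3 relapse aspirates come from 1 dog, so they measure spread within that dog and not between dogs. No chromosome position is given for any gene, since the reference assembly at hand differs from the one the array was built on.

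The series title names the anaphase promoting complex, the ubiquitin ligase that drives cells out of mitosis. Only 1357 gene symbols could be attached to the probes, and none of the 14 core subunits of the complex was among them. Of 16 activators and partner enzymes only UBE2S carried a symbol, and of 35 substrates only BIRC5 and CDC25A did, so no list for the complex could be tested. These 3 genes and the thymidylate synthase gene TYMS are given below as single values.

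**Figure D1:**
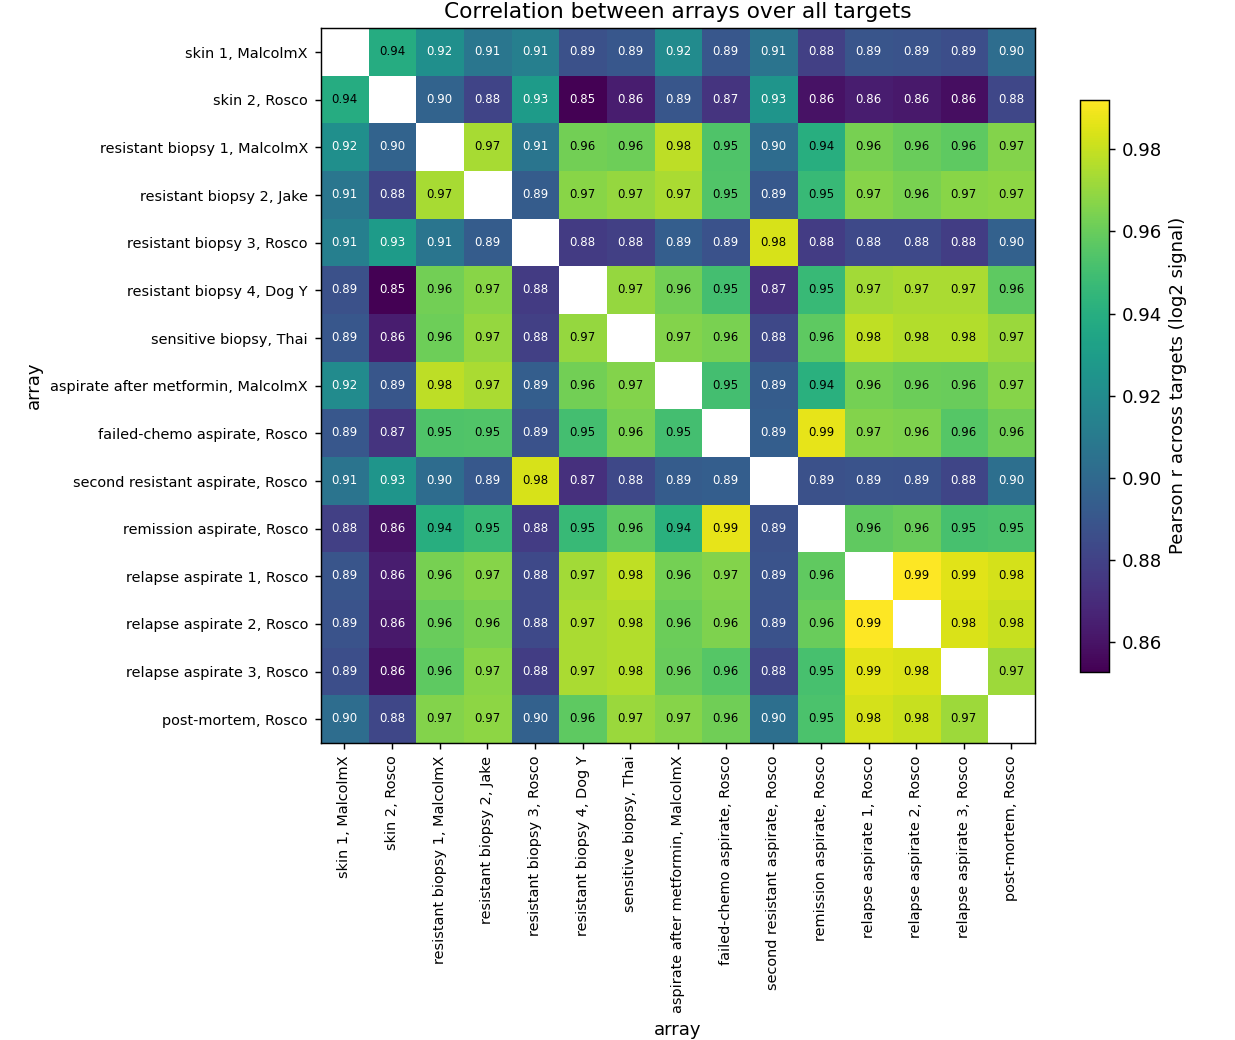
Pearson correlation across targets between each pair of the 15 arrays, with arrays labelled by group and dog and colour giving r. Values run from 0.853 to 0.992, and the first biopsy and second resistant aspirate of Rosco (0.984) and the failed-chemotherapy and remission aspirates (0.987) stand out as close pairs.

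Across targets, which are not independent replicates, the arrays fell into a few close sets. The first biopsy of Rosco had r = 0.984 with the second resistant aspirate of Rosco, and the failed-chemotherapy aspirate had r = 0.987 with the remission aspirate. The relapse aspirates had r between 0.984 and 0.992 with each other. MS4A1, which encodes the B cell surface protein CD20, lay between 1.78 and 3.53 in the relapse, post-mortem and sensitive samples, in the MalcolmX aspirate and in 3 of the resistant biopsies. It lay at −7.15 in the first biopsy of Rosco, −6.73 in the second resistant aspirate and −8.03 in Rosco skin. In the MalcolmX skin it was 0.84, and in the failed-chemotherapy and remission aspirates 0.41 and 0.38. Genes of exocrine gland epithelium went the other way, with CA6, a secreted carbonic anhydrase, at 8.60 in the first biopsy of Rosco and 9.0 in the second resistant aspirate against at most 1.46 on any other array.

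**Figure D2:**
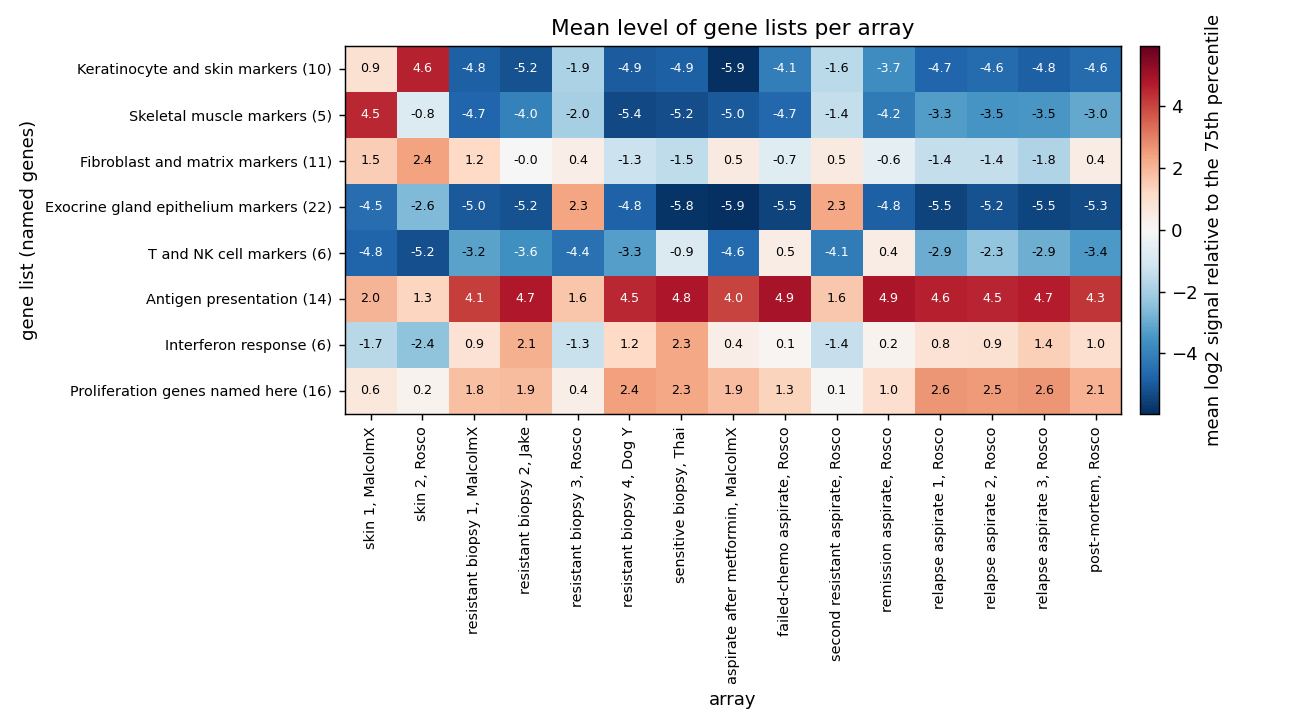
Mean log2 signal, relative to the 75th percentile of the array, of 8 gene lists on each of the 15 arrays. The exocrine gland list stands at 2.34 and 2.31 in the first biopsy and second resistant aspirate of Rosco, and the T and NK cell list at 0.45 and 0.44 in the failed-chemotherapy and remission aspirates.

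The resistant biopsies were compared with skin to ask what sets these tumours apart from the control tissue of the series. Genes of the epidermis were far lower in the 4 biopsies than in the 2 skin samples. KRT1, the keratin of differentiated epidermis, averaged −7.66 (SD 0.58, n = 4) in the biopsies and 6.82 (SD 2.05, n = 2) in skin. The difference of −14.48 (SE 0.84) corresponds to a level at least 15190-fold lower. KRTDAP, made by differentiating keratinocytes, fell by 10.66 (SE 0.76) and SPINK5, a protease inhibitor of the skin barrier, fell by 8.12 (SE 0.79). The desmosome gene DSG1 fell by 9.09 (SE 0.93, at least 307-fold) and the epidermal keratin KRT2 fell by 9.08 (SE 1.12). ADIPOQ, the fat cell hormone adiponectin, fell by 7.74 (SE 0.70), and FFAR4, a fatty acid receptor, fell by 7.67 (SE 0.36, at least 110-fold). GATM, which starts creatine synthesis, fell by 8.70 (SE 1.01), and the secreted antioxidant enzyme GPX3 fell by 5.36 (SE 0.68).

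By limma, 103 of 23921 targets were called, 2 higher and 101 lower in the biopsies, and neither of the 2 higher ones carried a gene symbol. Among 1044 named genes 14 were called, all lower, and for all 14 the groups did not overlap. Chance gives this for 13.3% of unselected genes, but genes past the threshold nearly always have separate groups, so it adds no support. The adjusted p of these 9 genes ran from 0.00355 for FFAR4 to 0.0466 for GPX3, with 0.00573 for KRT1. The median of all tested targets stood 0.24 higher in the biopsies, against which these differences should be read. The count depended on single arrays. Without the Rosco biopsy it was 3102 (1477 higher, 1625 lower), which included all 103. Without the MalcolmX, Jake or Dog Y biopsy it was 11, 5 or 21, and without the MalcolmX or Rosco skin 329 or 319, where the lone skin array left is assumed to vary like the others. FFAR4 passed without any single array, KRT1 missed without the Jake biopsy (−14.33, adjusted p = 0.0603), and KRTDAP, SPINK5, DSG1, KRT2, ADIPOQ, GATM and GPX3 missed without it at adjusted p of 0.0717 to 0.189 by limma. KRTDAP also missed without the MalcolmX biopsy (adjusted p = 0.0515) and ADIPOQ without the Dog Y biopsy (adjusted p = 0.0751). DSG1, KRT2, GATM, SPINK5 and GPX3 missed without either of these biopsies (0.0881 to 0.165), and GPX3 without either skin (0.0800 and 0.123).

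Slide 1 and slide 2 each held arrays of both groups. With slide as a block 32 targets were called, and within slide 1 alone 40, all lower. With the block, within slide 1 and within slide 2, KRT1 differed by −14.19, −13.04 and −15.92, KRTDAP by −10.27, −9.63 and −11.24, SPINK5 by −7.73, −6.88 and −9.0, DSG1 by −8.67, −7.41 and −10.57, and KRT2 by −8.60, −6.97 and −11.05. In the same order ADIPOQ gave −7.37, −7.88 and −6.61, FFAR4 −7.68, −8.09 and −7.05, GATM −9.06, −10.44 and −6.99, and GPX3 −5.28, −5.01 and −5.68. DSG1, KRT2, GATM and GPX3 missed the threshold with the block. Within slide 1 only KRT1 passed (adjusted p = 0.0490). There KRTDAP and FFAR4 had an adjusted p of 0.0502, DSG1, ADIPOQ, SPINK5, KRT2 and GATM of 0.0565 to 0.0724 and GPX3 of 0.372. Only MalcolmX and Rosco had both tissues. With these dogs alone and dog as a fixed block limma called 0 targets, with 2157 at an unadjusted p under 0.05, and with dog as a random block on all 6 arrays it called 150.

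**Figure D3:**
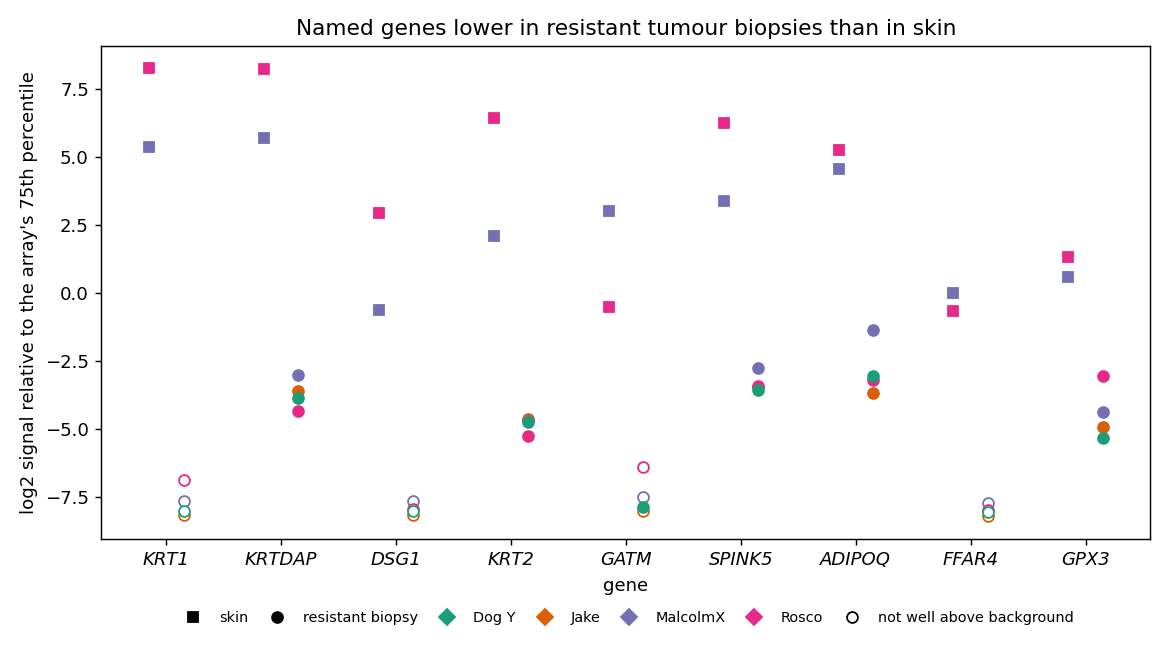
Log2 signal, relative to the 75th percentile of the array, of 9 named genes lower in the resistant biopsies than in skin, with 1 point per array. KRT1 averaged 6.82 in skin and −7.66 in the biopsies.

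At the preset correlation camera called lists of keratinocyte, muscle and matrix genes lower and some lists of immune and dividing cells higher, and none of these calls held with an estimated correlation. The list Keratinocyte and skin markers fell by 7.38 on average (9 genes, 3 called, 8 adjusted over the list alone, camera adjusted p = 5.01e-10, adjusted p = 0.379 with an estimated correlation). Skeletal muscle markers fell by 5.85 (5 genes, 0 called, 3 adjusted over the list alone, adjusted p = 0.000375 by camera and 0.379 with an estimated correlation). In that list MYH2, a fast muscle myosin, differed by −10.93 (SE 2.16) and MYL2, a slow muscle myosin light chain, by −6.53. Fibroblast and matrix markers fell by 1.87, with 10 of 11 genes lower and 1 called adjusted over the list alone (camera adjusted p = 0.000375, adjusted p = 0.379 with an estimated correlation). The matrix proteins DPT and DCN differed by −4.86 and −4.03, short of the threshold. Antigen presentation genes were higher by 2.09, all 14 of them (adjusted p = 0.000175, adjusted p = 0.465 with an estimated correlation). They include the class II gene DLA-DOB (+2.92) and the immunoproteasome gene PSMB8 (+2.54), and 0 passed adjusted over the list alone. The Interferon response list was higher by 2.73 in 6 of 6 genes (adjusted p = 0.00276, adjusted p = 0.400 with an estimated correlation), among them the chemokine CXCL10 (+3.49) and the antiviral gene MX1 (+2.94), and 1 passed adjusted over the list alone.

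The list T and NK cell markers was higher by 1.29 in 5 of 5 genes, with 3 called adjusted over the list alone (camera adjusted p = 0.00773, adjusted p = 0.379 with an estimated correlation). The chemokine CCL5 differed by 2.73 and CD4 by 1.55. Monocyte and macrophage markers were higher by 1.01 in 8 of 9 genes, with 2 called adjusted over the list alone (adjusted p = 0.0444, adjusted p = 0.379 with an estimated correlation). CYBB, the phagocyte oxidase, differed by 2.62 and the costimulator CD86 by 2.47. The list Proliferation genes named here, put together after some values had been seen, was higher by 1.21 in 15 of 15 genes (adjusted p = 0.00626, adjusted p = 0.620 with an estimated correlation). ASPM, a spindle protein, differed by 2.33. The macrophage call missed without the MalcolmX biopsy (0.97, adjusted p = 0.0503), the Rosco biopsy (1.03, 0.140) or the MalcolmX skin (0.67, 0.229), and the muscle call without the MalcolmX skin (−3.19, 0.0894). The macrophage value under quantile scaling, 1.05, and under normexp, 0.92, also missed.

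With slide as a block, and then within slide 1 and slide 2, the list values kept their signs. They were −7.21, −5.53 and −9.72 for keratinocytes, −6.52, −8.28 and −3.88 for muscle, and −1.56, −1.79 and −1.21 for fibroblasts. Antigen presentation gave 2.08, 1.59 and 2.83, interferon 2.69, 2.33 and 3.22, macrophages 1.11, 1.31 and 0.80. T and NK cells gave 1.31, 0.88 and 1.97 and proliferation 1.22, 0.98 and 1.57, and within slide 1 both of these had an adjusted p of 0.0681.

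Lists that camera did not call between biopsies and skin were Multidrug resistance transporters (mean −0.09, median 0.22), neutrophils (0.29), melanocytes (−1.05), glycolysis (0.16), apoptosis and p53 targets (0.84), DNA repair (1.16), redox and glutathione genes (−0.97) and ribosomal proteins (0.42, adjusted p = 0.0790). The added lists for exocrine gland (−0.90), T cell activation (1.08) and chemokines (1.06) were not called either. The lists Ribosomal proteins (0.49, adjusted p = 0.0296) and Chemokines (1.29, adjusted p = 0.0344) passed with slide as a block. The gland list had the opposite sign within slide 1 (0.78, adjusted p = 0.412), which holds the Rosco biopsy, and was −1.01 with the block. The transporter list also turned, to 0.39 within slide 2. ABCB1, the drug efflux pump P-glycoprotein, differed by 1.12 (adjusted p = 0.431), by 0.01 within slide 1 and by 2.55 within slide 2. The transporter ABCC1 differed by 0.38. BCL6, a repressor of germinal centre B cells, differed by −3.97 (at least 12.8-fold lower, adjusted p = 0.0635). BIRC5, UBE2S and TYMS differed by 1.47, 1.11 and 1.27, CDC25A by 1.39 (at least 1.88-fold), and MS4A1 by 4.0, with MS4A1 and CDC25A outside the test because they were dim on arrays of both groups. Within slide 1 MS4A1 had the opposite sign (−1.36) because of the Rosco biopsy at −7.15, since the Jake and Dog Y biopsies lay at 2.92 and 2.69 and the MalcolmX skin at 0.84. Within slide 2 it was at least 1447-fold higher.

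Without the Rosco biopsy, limma called 204 of 1057 named genes, 83 higher and 121 lower in the 3 remaining biopsies. FASLG, the death ligand of cytotoxic T cells, was higher by 4.76 (SE 0.83, adjusted p = 0.0303), BIRC3, an apoptosis inhibitor, by 4.75 (SE 0.75, adjusted p = 0.0255), and TLR1, a receptor for bacterial lipopeptides, by 4.16 (SE 0.75). The B cell costimulator CD40 was higher by 4.11 (SE 0.92), CXCL10 by 4.03 and DLA-DOB by 3.96. SLAMF1 was at least 10.8-fold higher, CCR3 at least 12.9-fold and TRIM34 at least 10.1-fold. The lower genes again included KRT1 (−14.75, at least 15981-fold), KRTDAP (−10.45), DSG1 (−9.09, at least 318-fold), GATM (−9.04) and KRT2 (−8.93). They were joined by the keratins KRT15 (−14.37, at least 12767-fold) and KRT19 (−10.22, at least 778-fold), the carboxylesterase CES1 (−14.05, at least 11266-fold), the muscle carbonic anhydrase CA3 (−13.07) and MYH2 (−12.36, at least 3722-fold). Leaving this array out was chosen before the data were examined as one of the alternatives that leave out each array in turn. Naming its genes was decided after its values were seen.

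The sensitive biopsy was compared with the resistant biopsies to ask how tumours with different responses to treatment differ. Among the biopsies, T cell genes stood highest in the sensitive one. The list T and NK cell markers was higher by a mean of 2.75 in 6 of 6 genes, with 5 called adjusted over the list alone (camera adjusted p = 1.48e-08, adjusted p = 0.376 with an estimated correlation). KLRD1, a receptor of NK cells, lay 3.88 (SE 1.34) above the resistant mean and the T cell costimulator CD28 lay 3.74 (SE 1.36) above it. The added list T cell activation and costimulation genes was higher by 1.82 in 17 of 18 genes, with 2 adjusted over the list alone (adjusted p = 3.67e-06, adjusted p = 0.509 with an estimated correlation). In it the cytokine IL21 differed by 5.41 (SE 1.19) and IFNG, the interferon made by T and NK cells, by 4.78 (SE 0.45, at least 15.4-fold). CD8A, the marker of cytotoxic T cells, differed by 2.65 (SE 0.46) and was picked after its values were seen.

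Other immune lists were higher as well. Monocyte and macrophage markers were higher by 0.81 in 8 of 9 genes (adjusted p = 0.0112, adjusted p = 0.376 with an estimated correlation), with the Fc receptor chain FCER1G at 2.08 and CYBB at 1.23. The Interferon response list was higher by 1.57 in 6 of 6 genes (adjusted p = 0.0469, adjusted p = 0.660 with an estimated correlation), with CXCL10 at 4.66 (SE 1.16) and OASL at 1.62. Antigen presentation genes were higher by 1.09 in 14 of 14 (adjusted p = 0.0177, adjusted p = 0.660 with an estimated correlation), with PSMB8 at 1.90 and DLA-DMB at 1.78. Erythroid and platelet markers were higher by 1.11 in 4 of 5 genes (adjusted p = 0.00708, adjusted p = 0.376 with an estimated correlation), with EPB41, a protein of the red cell skeleton, at 1.24. The added Chemokines list was higher by a mean of 0.94, though only 9 of 17 genes were (adjusted p = 0.0456, adjusted p = 0.656 with an estimated correlation), with CXCL10 and CCL3 (4.51, SE 1.00) the farthest apart.

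Fibroblast and matrix markers fell by 1.57 in the sensitive biopsy, with 10 of 11 genes lower and 0 adjusted over the list alone (adjusted p = 0.000325, adjusted p = 0.471 with an estimated correlation). The matrix genes DCN and FBN1 differed by −5.77 and −2.34. The added Exocrine gland epithelium markers fell by 1.86 in 11 of 11 genes (adjusted p = 0.00942, adjusted p = 0.656 with an estimated correlation), with CA6 at −3.92 and SPINT2 at −2.65. That difference rested on the Rosco biopsy, the 1 resistant biopsy with high gland genes, and without it the value was −0.37 (adjusted p = 0.152). Without the Rosco biopsy the calls were also lost for erythroid genes (0.95, adjusted p = 0.0883), interferon (0.89, 0.160), antigen presentation (0.39, 0.100) and chemokines (0.88, 0.0516). The interferon call was lost too without the MalcolmX biopsy (1.62, 0.0616) or the Dog Y biopsy (1.73, 0.0683), and the chemokine call without the Dog Y biopsy (0.75, 0.448). The calls for T and NK cells, T cell activation, macrophages and fibroblasts passed without any 1 of the resistant biopsies.

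By limma 0 of 26344 targets were called between the sensitive and resistant biopsies, with 785 at an unadjusted p under 0.05. The lone sensitive array is assumed to vary like the resistant ones. In simulated data of this design 0 of 50 targets changed by 16-fold were recovered, so the test could not call genes at this spread. The adjusted p was 0.999 for KLRD1. ABCB1 differed by 0.10 (SE 0.74), ABCC1 by 0.76, MS4A1 by 3.13 (SE 4.26) and BCL6 by 1.49 (at least 2.30-fold higher). The MS4A1 difference rests on the Rosco biopsy at −7.15. The sensitive biopsy stood at 3.53 against 2.69 to 3.18 in the other 3 resistant biopsies. BIRC5 differed by 1.56 (SE 1.19), CDC25A by 1.53, UBE2S by 1.55 and TYMS by 0.51. In the Rosco biopsy BIRC5 and UBE2S were at −0.51 and −0.05, against 1.96 and 1.72 in the MalcolmX biopsy. Uncalled lists were transporters (0.36), neutrophils (0.38), keratinocytes (mean 0.16, median −0.15), melanocytes (−0.13), glycolysis (−0.23), apoptosis (0.34), DNA repair (0.65), redox (0.23), ribosomal proteins (−0.14) and proliferation (0.68, adjusted p = 0.0596). No slide held both groups, and the sensitive array was scanned on the second day and all 4 resistant ones on the first, so scan day and group cannot be told apart. With slide as a random block the list values were 2.85 for T and NK cells, 1.98 for T cell activation, 0.84 for macrophages, 1.11 for erythroid genes, 1.61 for interferon, 1.17 for antigen presentation, 1.08 for chemokines, −1.32 for fibroblasts and −2.21 for the gland list. The proliferation list, uncalled above, passed with this block (0.71, adjusted p = 0.0354). The median of all tested targets moved by 0.08, or by 0.13 under quantile scaling and −0.10 with the deposited matrix values.

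The remission aspirate of Rosco was compared with the other 5 aspirates of the same dog to ask what marks the tumour site in remission after metformin. T cell genes stood high in it, and also in the aspirate taken before metformin. The list T and NK cell markers was higher by 2.81 in 6 of 6 genes (camera adjusted p = 0.0485, adjusted p = 0.947 with an estimated correlation), with CD28 at 5.09 (SE 2.56) and CD8A at 5.02 (SE 2.64) above the mean of the others. The added list T cell activation and costimulation genes was higher by 2.68 in 15 of 18 genes (adjusted p = 0.00275, adjusted p = 0.966 with an estimated correlation), with the lymphocyte surface protein CD52 at 6.13 (SE 3.65). The added list Proliferation genes named here fell by 0.84, with 14 of 16 genes lower (adjusted p = 0.00275, adjusted p = 0.966 with an estimated correlation), and the centromere protein CENPS and ASPM differed by −1.64 and −1.47. The T and NK list averaged 0.44 in the remission aspirate and 0.45 in the failed-chemotherapy aspirate, against −4.14 to −2.35 in the relapse and second resistant aspirates.

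Limma called 0 of 26074 targets here, with 876 at an unadjusted p under 0.05, and the lone remission array is assumed to vary like the others. In simulated data of this design 0 of 50 targets changed by 16-fold were recovered. The T and NK call was lost without relapse aspirate 1 (2.67, adjusted p = 0.0565), relapse aspirate 3 (2.68, 0.0757) or the second resistant aspirate (2.37, 0.0760), and without the latter the T cell activation call was lost too (1.98, 0.0820). The T and NK value with slide as a block and within slide 4 was 3.57, that of T cell activation 3.50 and that of proliferation −0.75, with CD28 at 6.37, CD8A at 6.47, CD52 at 8.25 and CENPS at −2.01. The slides give 1 value for both because only slide 4 holds both groups. The failed-chemotherapy aspirate lies on slide 3 and drops out of these values, with a T and NK mean of 0.45 against 0.44 in remission. The larger T cell values therefore show no rise over that aspirate. Uncalled lists were transporters (0.99), macrophages (mean 0.04, median −0.16, lower in the test), neutrophils (1.69, adjusted p = 0.0910), fibroblasts (mean 0.51, lower in the test), keratinocytes (0.78), melanocytes (mean −0.11, median 0.06), erythroid genes (1.20) and glycolysis (mean 0.22, median −0.11, lower in the test). The same held for interferon (−0.18), apoptosis (0.48), DNA repair (−0.74), redox (−0.02), antigen presentation (0.81), ribosomal proteins (0.19), germinal centre genes (mean 0.11, median −0.13, lower in the test), the gland list (−0.15) and chemokines (mean 0.12, lower in the test). ABCB1 differed by 2.96 (SE 1.86), ABCC1 by −0.53, BCL6 by 1.65, BIRC5 and UBE2S by −1.18 each and TYMS by −1.34. CDC25A differed by 0.13 and MS4A1 by 0.39 (SE 3.36), and both had the opposite sign under normexp, CDC25A also under quantile scaling. The median of all tested targets stood 0.15 higher in the remission aspirate.

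Against the 3 relapse aspirates alone, an alternative fixed before the data were examined, 5536 of 26408 targets were called by limma, 2877 higher and 2659 lower in remission. The remission group is 1 array and the spread comes only from 3 close arrays of the same dog, so a call places this array outside that spread and does not show what remission does. Set against the same 3 arrays, the failed-chemotherapy aspirate gave 3770 calls and the second resistant aspirate 12105. CD52 rose by 6.5 (SE 0.59, adjusted p = 0.00736), CD8A by 6.27 (SE 0.45, adjusted p = 0.00558), CD28 by 5.55 (adjusted p = 0.00558), the receptor chain IL12RB2 by 6.20 and SLAMF1 by 5.25. IL2, the T cell growth factor, rose by 5.19 and CD40LG, the helper T cell ligand of CD40, by 4.98. REG3A, a secreted lectin, rose by 5.69, the aldehyde oxidase AOX2 by 5.21 and SLC15A1, a peptide transporter, by at least 10.4-fold. ABCB1 rose by 4.10 and BCL6 by at least 3.29-fold. Genes active in dividing cells were lower, with BIRC5 at −2.26, UBE2S at −2.14, TYMS at −2.07 and ASPM at −2.30, and MS4A1 fell by 1.72 (adjusted p = 0.0256, with others of its alternatives up to 1.00), the reverse of its sign against all 5 aspirates. OOEP, known from oocytes and embryos, fell by 6.88 (SE 0.24, adjusted p = 0.00435), and RHPN2 (−5.93), OAZ3 (−5.75), GUCY1B1 (−4.77), the B cell Toll-like receptor TLR10 (−4.64), BHLHE41 (−4.60) and SLC6A12 (−4.27) were lower too. TFAP2B was at least 44.2-fold lower, EDN3 at least 21.1-fold and CYP3A26 at least 4.65-fold. Against the failed-chemotherapy and second resistant aspirates alone, limma called 0 targets, with 157 at an unadjusted p under 0.05, and the list Proliferation genes named here had the opposite sign (0.29, adjusted p = 0.734, with 1.12e-07 to 0.966 over all its alternatives).

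**Figure D4:**
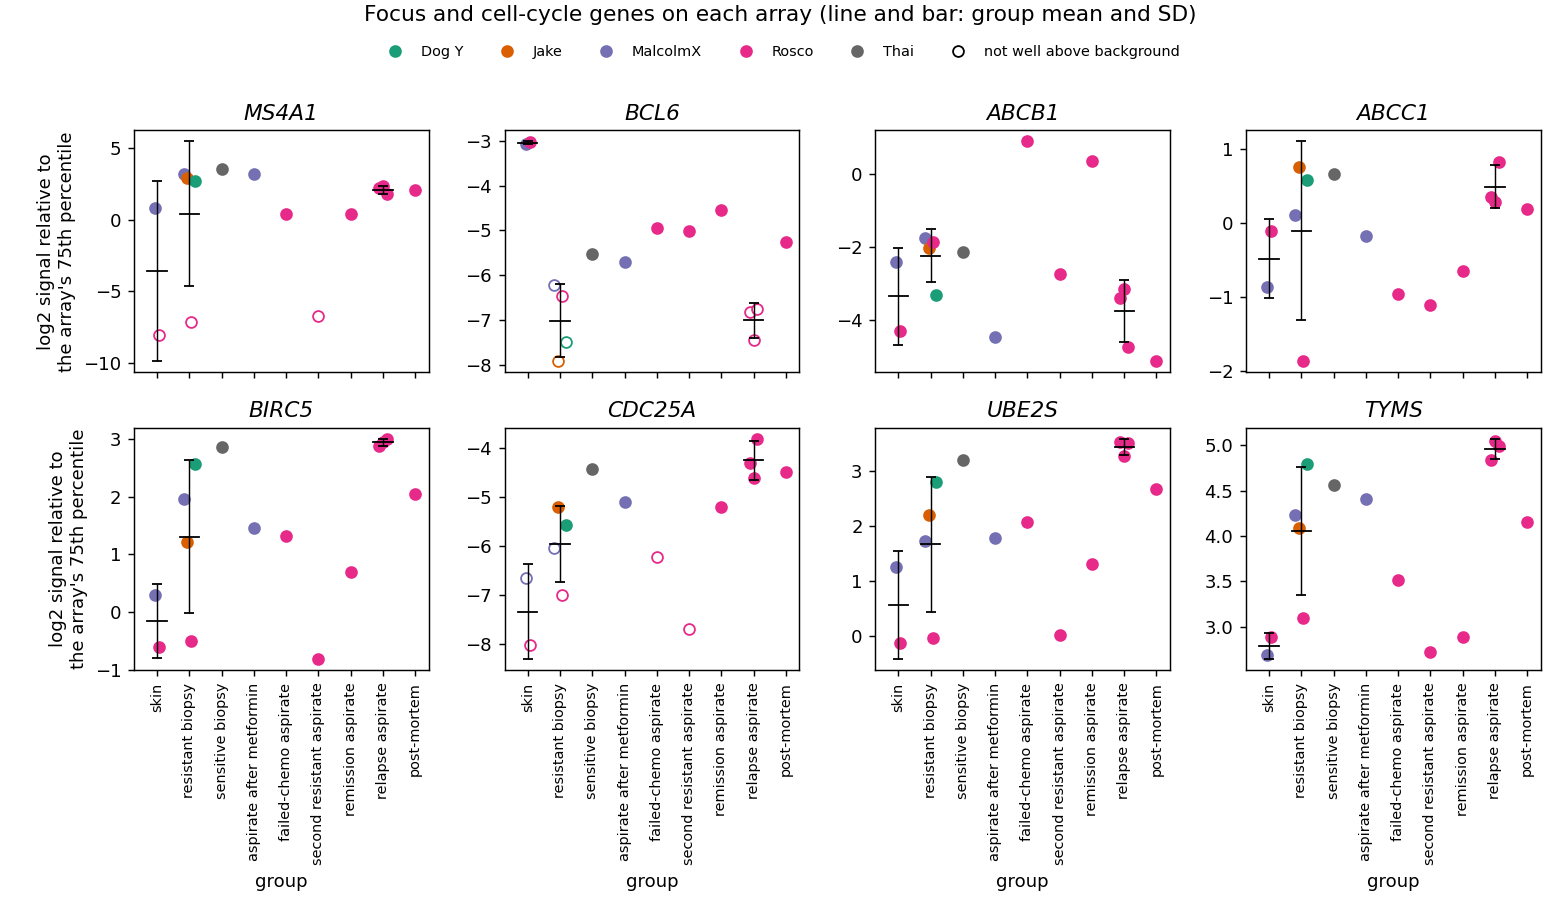
Log2 signal of MS4A1, BCL6, ABCB1, ABCC1, BIRC5, CDC25A, UBE2S and TYMS on each array by group, relative to the 75th percentile of the array. Open circles mark arrays where the probe is not well above background, and lines and bars give the group mean and SD.

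The relapse aspirates were compared with the 2 earlier aspirates of Rosco, the failed-chemotherapy aspirate and the second resistant aspirate. The aim was to ask what differs in the samples labelled relapse after metformin, whose titles read no remission. The label of the second resistant aspirate says nothing of metformin, so counting it as earlier is an assumption. By limma OOEP rose by 6.28 (SE 0.38, adjusted p = 0.0120), the B cell gene TLR10 by 5.41 (SE 0.53, adjusted p = 0.0243), CD1A8, a lipid antigen presenter, by 4.55 (adjusted p = 0.0209) and OAZ3 by 4.55 (adjusted p = 0.0448). The antiviral genes MX1 and OAS2 rose by 3.98 (SE 0.26, adjusted p = 0.0130) and 2.55 (SE 0.31, adjusted p = 0.0366). The transporter SLC6A12 rose by 4.23, the potassium channel KCNJ12 by 3.57, the adenosine receptor ADORA2B by 3.38 and CYP3A26 by at least 12.4-fold. MMP12, a macrophage elastase, fell by 4.29 (adjusted p = 0.0181). ANXA2 (−4.38), the growth factor BMP4 (−3.49), the matrix protein TNC (−2.19) and the muscle protein UTRN (−1.97) were lower too. CA3 fell by 6.56 (SE 0.94, adjusted p = 0.0434), with −3.11 as the mean of its probes, and PPFIBP1 was at least 6.62-fold lower. B4GALT4 fell by 4.16 (adjusted p = 0.0482), and its other probe had the opposite sign (0.69). ABCC5, an efflux transporter, fell by 2.85 (adjusted p = 0.0473).

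By limma 586 of 24660 targets were called, 302 higher and 284 lower at relapse. Of 1027 named genes 33 were called, 22 higher and 11 lower, and in all 33 the groups did not overlap. Chance gives this for 20% of unselected genes, but genes past the threshold nearly always have separate groups, so it adds no support. The count was 0 without relapse aspirate 1, 2 or 3, with 3314, 3444 and 4134 at an unadjusted p under 0.05. It was 12105 without the failed-chemotherapy aspirate and 3770 without the second resistant aspirate, where the lone array left is assumed to vary like the others. With slide as a block it was 120 and within slide 4 alone 8513. Without each relapse aspirate OOEP differed by 6.33, 6.22 and 6.29 and MX1 by 4.04, 3.99 and 3.92, and no adjusted p was under 0.05. With the block, within slide 4 and within slide 3, OOEP differed by 6.34, 6.84 and 5.67, TLR10 by 5.53, 6.26 and 4.56, MX1 by 3.96, 4.0 and 3.91, CD1A8 by 4.44, 4.34 and 4.56, SLC6A12 by 4.23, 3.94 and 4.61, and MMP12 by −4.29, −4.81 and −3.59. These 6 genes passed with the block, and the others described here, with values between −6.67 for CA3 and 4.37 for OAZ3, missed. The 3770 targets called without the second resistant aspirate included all 586. OOEP rose by 5.78 there, RHPN2 by 5.77, OAZ3 by 5.66, MX1 by 4.02 and TFAP2B by at least 43.6-fold, while REG3A, CA3, CD52 and CD8A were lower (−7.15, −6.82, −6.71 and −6.58).

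The list Proliferation genes named here was higher at relapse by 1.89 in 16 of 16 genes, with 0 called over all targets and 13 adjusted over the list alone (camera adjusted p = 5.54e-07, adjusted p = 0.671 with an estimated correlation). With slide as a block it was 1.98, within slide 4 2.49 and within slide 3 1.30. Part of the rise rests on the second resistant aspirate, which had high gland and low B cell genes and a list mean of 0.08, against 1.32 in the failed-chemotherapy aspirate. Without it the value was 1.27 (adjusted p = 2.22e-06). The Interferon response list was higher by 1.69 in 6 of 6 genes, 2 of them called (adjusted p = 0.0436, adjusted p = 0.627 with an estimated correlation), at 1.77 with the block, 2.54 within slide 4 and 0.74 within slide 3. Its call was lost without relapse aspirate 3 (1.51, adjusted p = 0.0752), without the second resistant aspirate (0.95, 0.459) and under quantile scaling (1.74). The added Exocrine gland epithelium markers fell by 3.08 in 10 of 10 genes (adjusted p = 0.0187, adjusted p = 0.788 with an estimated correlation), with the secreted proteins CA6 and SLPI at −8.05 and −4.64. They differed by −3.50 with the block, by −8.28 within slide 4, where 20 genes were tested, and by −0.37 within slide 3. Without the second resistant aspirate the gland value was −0.26 (adjusted p = 0.708), and without relapse aspirate 3 it was −2.56 (0.0658).

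BIRC5, the survivin gene of mitotic cells, differed by 2.69 (SE 0.65, adjusted p = 0.0943) and UBE2S, the ubiquitin-chain elongating enzyme of the anaphase promoting complex, by 2.40 (adjusted p = 0.110). CDC25A, a phosphatase that starts S phase, differed by 2.71 (at least 6.53-fold, adjusted p = 0.0698), TYMS by 1.84 (adjusted p = 0.0629) and ABCC1 by 1.53 (adjusted p = 0.0698). ABCB1 differed by −2.83 (adjusted p = 0.207), BCL6 by −2.03 (at least 2.44-fold lower, adjusted p = 0.0510) and MS4A1 by 5.26 (adjusted p = 0.191). Within slide 3, against the failed-chemotherapy aspirate, the differences were 1.57 for BIRC5, 1.46 for UBE2S, 1.32 for TYMS, 1.32 for ABCC1, −4.27 for ABCB1 and 1.77 for MS4A1, with CDC25A at least 3.75-fold higher and BCL6 at least 3.66-fold lower. Within slide 4, against the second resistant aspirate alone, BIRC5 was higher by 3.79, UBE2S by 3.39, TYMS by 2.30 and ABCC1 by 1.67. CDC25A was at least 11.1-fold and MS4A1 at least 442-fold higher there, BCL6 was at least 1.96-fold lower, and CA6 (−15.25) and SLPI (−7.67) were lower too. All of these were called within slide 4, but they rest on 1 array with high gland genes and MS4A1 at −6.73, so they cannot be read as a change at relapse. Without the second resistant aspirate MS4A1 rose by 1.69, BIRC5 by 1.62, TYMS by 1.44, ABCC1 by 1.45, UBE2S by 1.37 and CDC25A by at least 3.92-fold. Without the failed-chemotherapy aspirate BIRC5 rose by 3.76, TYMS by 2.24, ABCC1 by 1.60, UBE2S by 3.44, MS4A1 by at least 454-fold and CDC25A by at least 10.9-fold, with the same array as the only one compared. BCL6 was at least 2.51-fold and 2.37-fold lower in these settings, and ABCB1 fell by 4.64 without the second resistant aspirate. Within slide 4, against the second resistant aspirate alone, ABCB1 differed by −1.21. ABCB1 stood at 0.88 in the failed-chemotherapy aspirate and at −2.73 in the second resistant aspirate, so its fall rests mainly on the former.

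Lists not called at relapse were transporters (−0.84, with ABCC5 the 1 gene called), T and NK cells (−0.89, with −0.59 for the slide block, 1.51 within slide 4 and −3.39 within slide 3), macrophages (0.63), neutrophils (−0.45), fibroblasts (−1.34, adjusted p = 0.0818), keratinocytes (−1.87, adjusted p = 0.0521), melanocytes (−0.23) and glycolysis (mean −0.04, median 0.02, higher in the test). Apoptosis (0.51), DNA repair (1.51, adjusted p = 0.0521), redox (−0.58), antigen presentation (1.36, adjusted p = 0.0620), ribosomal proteins (0.47, adjusted p = 0.0620), T cell activation (−0.47) and chemokines (−0.25) were not called either. Adjusted together with the added lists, keratinocytes and DNA repair pass at an adjusted p of 0.0402 each. Camera called 4 of these lists with slide as a block, keratinocytes (−1.97, adjusted p = 0.0201), DNA repair (1.63, 0.0166), antigen presentation (1.60, 0.0166) and ribosomal proteins (0.54, 0.0296). These 4 also passed within slide 4, and so did T cell activation with the opposite sign (1.78, adjusted p = 0.00187), where the second resistant aspirate is the only earlier array. Within slide 3 antigen presentation and apoptosis had the opposite sign (−0.30 and −0.14). The median of all tested targets moved by 0.04, and by 0.17 under quantile scaling.

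The tumour sample taken after the death of Rosco was compared with the relapse aspirates to ask how the tumour at the end of the disease differs from the relapse before it. The label does not say how the post-mortem tissue was taken. Matrix genes were higher after death. Fibroblast and matrix markers were higher by 1.98 in 9 of 11 genes, with 8 called adjusted over the list alone (camera adjusted p = 0.000135, adjusted p = 0.801 with an estimated correlation). DCN, a collagen-binding proteoglycan, differed by 5.08 (SE 0.87, adjusted p = 0.109) and the collagen chain COL1A1 by 4.10 (SE 0.41, adjusted p = 0.0549). COL1A1 passed under normexp (3.91, adjusted p = 0.0424) and without relapse aspirate 1 (4.31, 0.0460), with 0.0424 to 1.00 over all its alternatives. T cell and cell division genes were lower. T and NK cell markers fell by 0.68 in 6 of 6 genes (adjusted p = 0.0438, adjusted p = 0.899 with an estimated correlation), with KLRD1 at −1.64 and CD28 at −1.18. Antigen presentation fell by 0.33 in 11 of 14 genes (adjusted p = 0.0397, adjusted p = 0.801 with an estimated correlation), with the class II genes DLA-DMB at −1.06 and DLA-DMA at −0.91.

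The added list T cell activation and costimulation genes fell by 0.56, with 17 of 19 genes lower (adjusted p = 0.00399, adjusted p = 0.767 with an estimated correlation), FASLG at −1.33 among them. The added list Proliferation genes named here fell by 0.53, with 13 of 16 genes lower (adjusted p = 6.99e-05, adjusted p = 0.687 with an estimated correlation), among them the histone gene H2AZ1 (−1.02) and the nuclear transport gene RAN (−0.90). Slide 3 held both groups, with the post-mortem sample and relapse aspirate 1. There and with slide as a block fibroblast genes differed by 1.88, antigen presentation by −0.34, T cell activation by −0.58, proliferation by −0.56, and T and NK cells by −0.47, the last with an adjusted p of 0.101. DCN differed by 5.18 there, COL1A1 by 3.69 and KLRD1 by −1.34. The T and NK call was also lost without relapse aspirate 2 (−0.49, adjusted p = 0.0744), and the antigen presentation call without relapse aspirate 1 (−0.33, 0.0506), under quantile scaling (−0.22) and under normexp (−0.21).

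Limma called 0 of 27118 targets between the post-mortem and relapse samples, with 4132 at an unadjusted p under 0.05, and the lone post-mortem array is assumed to vary like the relapse ones. In simulated data of this design 28 of 50 targets changed by 4-fold and 49 of 50 changed by 8-fold were recovered. The simulated spreads were already shrunk toward a common value, which can overstate recovery. COL1A1 and DCN differed by more than 8-fold and were not called, so the count of 0 does not exclude such changes. The count was 107 without relapse aspirate 1 and 431 without relapse aspirate 3. ABCB1 differed by −1.36, ABCC1 by −0.30, BCL6 by 1.74 (at least 2.00-fold higher), BIRC5 by −0.90, CDC25A by −0.24, UBE2S by −0.76 and TYMS by −0.81. MS4A1 differed by −0.05, with the opposite sign under normexp (0.06) and quantile scaling (0.11). Uncalled lists were transporters (mean 0.23, median −0.04), macrophages (0.38), neutrophils (−0.45), keratinocytes (0.39), melanocytes (mean 0.00, median 0.29, lower in the test), glycolysis (−0.19), interferon (−0.04), apoptosis (−0.19), DNA repair (mean −0.02, median 0.13), redox (mean 0.02, median −0.12, lower in the test), ribosomal proteins (−0.14), the gland list (0.49) and chemokines (0.83). Interferon turned to 0.17 and redox to −0.03 with slide as a block.

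Some pairs of single arrays from 1 dog were compared without a test, and their values carry no error. The random lists hold unrelated genes, while genes of a tested list can vary together. Their percentiles are therefore descriptive and not p-values. The MalcolmX aspirate after metformin was set against the first biopsy of that dog, on the same slide, to show the tumour before and after the drug. The pair also differs in how the tissue was taken, by needle or by biopsy, which is not separated from the drug here. The lowest signal well above background was −9.05 in the aspirate and −6.69 in the biopsy, and whether this gap makes dim genes read lower in the aspirate was not tested. Among named genes the lowest were CD52 at −4.63, the antimicrobial peptide gene CAMP at −4.21, the matrix protease MMP9 at −3.75, the lymph node chemokine CCL21 at −3.71 and the mast cell receptor FCER1A at −3.66. Under normexp these were −1.68, −2.86, −2.03, −2.44 and −2.00. CA3 (4.75), the gluconeogenic enzyme PCK1 (4.40), HSP70 (2.43), ADIPOQ (2.17) and the glutamate transporter SLC1A3 (2.05) were higher. Of 23183 targets 2102 differed by 2-fold or more, 340 higher and 1762 lower. The median difference of neutrophil genes was −2.12, lower than that of any of 10000 random lists matched in expression. That of chemokines was −1.64, also below all random lists, that of macrophages −0.75 (percentile 0.02), that of T and NK cells −1.19 (percentile 0.44) and that of T cell activation −0.39 (percentile 0.68). Lists of other tissue were lower too, with the gland list at −0.68 (percentile 0.17) and melanocytes at −0.67 (percentile 1.64). The proliferation median was 0.05 (percentile 66.7). ABCB1 was at −2.72 (−1.41 under normexp), ABCC1 at −0.28, MS4A1 at 0.04, BCL6 at 0.52 (0.15 under normexp, not well above background in the biopsy), BIRC5 at −0.50, TYMS at 0.18 and UBE2S at 0.06, the last at −0.03 under normexp.

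The remission aspirate of Rosco was set against the failed-chemotherapy aspirate, on another slide, to show the same dog before metformin and in remission after it. Neutrophil and monocyte genes were higher in remission, with the neutrophil chemokine CXCL8 at 4.19, SERPINA1 at 2.64, the Fc receptor FCGR1A at 2.62 and the neutrophil protein S100A8 at 2.08, along with OPN1LW at 2.22. CA3 (−3.67), the monocyte chemokine CCL2 (−2.85), IL21 (−2.83), the fatty acid receptor CD36 (−2.61) and the endothelial adhesion gene SELE (−2.28) were lower. Of 24808 targets 1122 differed by 2-fold or more, 756 higher and 366 lower, or 608 and 536 under quantile scaling. The median was 0.73 for neutrophil genes (percentile 99.9), 0.51 for macrophages (percentile 99.96), 0.56 for interferon (percentile 99.96) and 0.76 for the gland list (percentile 99.99). It was −0.37 for proliferation and −0.50 for chemokines, both below all 10000 random lists, and −0.43 for DNA repair (percentile 0.74). The T and NK median was 0.15 (percentile 90.7), while the mean was −0.01. BIRC5 was at −0.63, UBE2S at −0.77, TYMS at −0.63, ABCB1 at −0.54, ABCC1 at 0.31 and MS4A1 at −0.02, the last at 0.03 under normexp. CDC25A was higher, at 1.02 (0.29 under normexp, not well above background in the failed-chemotherapy aspirate). BCL6 was at 0.39, and at −0.0003 under normexp.

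The second resistant aspirate of Rosco was set against the first biopsy of the same dog, on another slide, to show how far these samples of the same description, 1 by needle and 1 by biopsy, differ. MSX2 (2.32), OR52N2G (2.25), IL10 (2.25), SLAMF1 (2.05) and OR2T11 (2.04) were higher, and SPCS2 (−1.21), VCAM1 (−1.18), TPMT (−1.03), ARSK (−1.01) and CREM (−1.01) lower. Of 23933 targets 2018 differed by 2-fold or more, 1885 higher and 133 lower. Under quantile scaling the split was 1184 higher and 587 lower. Redox genes had a median of −0.39 (percentile 0.84), proliferation −0.34 (percentile 1.2) and chemokines −0.26 (percentile 0.46). ABCB1 was at −0.87, ABCC1 at 0.75, BIRC5 at −0.31, UBE2S at 0.05 and TYMS at −0.38. BCL6, not well above background in the biopsy, was at 1.44, and at 0.15 under normexp. MS4A1, not well above background on either array, was at 0.42, and at −0.10 under quantile scaling.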

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

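All tests in this part were chosen after the result they explain was seen, except the one for a sample of another dog. For that one the bound was written first, but the reading of a tie was settled after the value was seen. The scan day test and the test of a lower B cell share in the sensitive biopsy replaced first versions whose values had been seen.

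Within the 4 resistant biopsies, 65 items (20 lists and 45 genes) were checked for 1 array far from the rest, by the gap to its neighbour over the whole range, against Dixon's 95% critical value. Chance finds about 1 in 20, or 3.25 here, and 6 were found, 5 of them in the Rosco biopsy. The items overlap and some were picked from the values of these arrays, so the excess over chance supports nothing. The Exocrine gland epithelium markers averaged 2.34 in the Rosco biopsy against −5.17 to −4.81 in the others (ratio 0.953). The Keratinocyte and skin markers averaged −1.90 there against −5.16 to −4.83 (ratio 0.901). MS4A1 was −7.15 against 2.69 to 3.18 (ratio 0.952). MYH2 was −1.91 against −8.20 to −7.34 (ratio 0.864), and SPINT2, an epithelial protease inhibitor, was 3.44 against −0.75 to −0.19 (ratio 0.866). SPINK5 was −2.75 in the MalcolmX biopsy against −3.56 to −3.42 (ratio 0.835).

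The first pattern is high gland genes with low B cell genes in the first biopsy and the second resistant aspirate of Rosco, where 20 of 22 gland genes were well above background on both arrays. A slide or scan day effect is argued against by the design, since these arrays lie on slides 1 and 4, read on different days. The lower of both stands 6.81 log2 units above the highest other array of the same slides, 2.31 against −4.50. The pattern was picked because these arrays stood apart, so this gap adds no support of its own. Tumour diluted by gland tissue, with 10% or more of the tumour left, is argued against as well. MS4A1 lies at least 8.51 below the lowest relapse aspirate of the same dog, or at most at 0.273% of that level. LTB lies 7.19 below and CD40 only 4.37, where 10% corresponds to 3.32. This reading takes the tumour in these samples to express these genes at the relapse level, which was not tested. A sample of another dog cannot be told apart from Rosco tissue, since both arrays fell on the Rosco side at 88.9% of 9 probes that separate the dogs, as the Thai array did, and 9 probes decide little. A candidate explanation left open is that these samples hold mostly gland tissue and few tumour cells, and no biological explanation was tested.

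The second pattern is high T cell genes in the failed-chemotherapy and remission aspirates of Rosco. A slide effect is argued against by the design, since these aspirates lie on different slides, 3 and 4. The lower of both stands 1.32 above the highest other array of the same slides. The pattern was picked because these aspirates stood highest, so this gap adds no support of its own. A lower share of tumour B cells in an otherwise unchanged mix of cells is argued against, since it would raise other cell types alike. The T and NK list rose by 3.18 over the relapse aspirates, the neutrophil list by 1.36 and the fibroblast list by 0.88. The macrophage list stood at −0.46, a gap of 3.64 (SE 0.984 over genes, which are not replicates). MS4A1 and CD40 were lower than at relapse (−1.70 and −2.59), so a lower B cell share with a changed mix stays open. Metformin or remission as the whole cause is argued against, since the aspirate taken before metformin had the same level (remission minus failed chemotherapy −0.0145). The data are consistent with more T cells at the site on both occasions, which stays a hypothesis found and tested on the same arrays, since where in the body each aspirate was taken was not tested.

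The third pattern is higher T cell genes in the sensitive biopsy than in the resistant ones. A lower share of tumour B cells in an otherwise unchanged mix of cells is argued against. The T and NK list rose by 1.94 more than the macrophage list (SE 0.559 over genes, which are not replicates) and fibroblast genes were lower (−1.57). A lower B cell share with a changed mix cannot be judged from these lists. MS4A1 was not lower in the sensitive biopsy, at 3.53 against 2.69 to 3.18 in 3 resistant biopsies and −7.15 in the Rosco one. This is 1 gene on 1 sensitive array, so it does not settle the B cell share. Scan day cannot be told apart from the group by the design. The 4 post-mortem and relapse samples of Rosco, read on the second day, stood 0.73 (SE 0.360 over arrays) above the resistant biopsies of the first day. The bound was 1.37, within 2 standard errors. These 4 samples come from 1 dog, so the error does not measure spread between dogs. The first-day group includes the Rosco biopsy with high gland genes, its lowest array at −4.44, which enlarges the value and the error. The test therefore decides nothing. With the other 3 aspirates of Rosco read that day, left out because they carry the patterns above, the value is 1.51 (SE 0.751). Whether the dog or its response may underlie the rest was not tested, since there is 1 sensitive dog.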

How the results depend on the processing

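The tests reported here with fits within 1 slide, with other arrays as the lone one, or with added lists were chosen after the results were seen, and the other alternatives were planned. For biopsies against skin, 103 targets were called. The count was 58 with normexp, 65 with no filter, 6 with a filter on every array, 648 with all 15 arrays in 1 fit, 32 with slide as a block, 40 within slide 1 and 5 to 3102 when each array was left out. With only the 2 dogs that gave both tissues and dog as a fixed block limma called 0, with 2157 at an unadjusted p under 0.05. It stayed within 1.5 times with quantile scaling (104), series values (92), probe means (106), a trended spread (69) and dog as a random block (150). For the sensitive biopsy limma called 0 (785 unadjusted), 11 with all 15 arrays in 1 fit, 4556 with the Rosco biopsy as the lone array, and 0 in the other settings, leaving out each array included, with 478 to 1881 unadjusted. For remission it called 0 (876 unadjusted), 85 with all arrays in 1 fit and 5536 against relapse alone. With relapse aspirate 3 as the lone array it called 1 and with the second resistant aspirate 5968, and in the other settings 0 (88 to 2766 unadjusted). Against relapse alone MS4A1 reversed to −1.72, and the proliferation list reversed to 0.29 against the 2 earlier aspirates alone. For relapse, 586 became 115 with no filter, 303 with a filter on every array, 8 with all arrays in 1 fit, 120 with slide as a block, 8513 within slide 4 and 0 to 12105 when each array was left out, the 0 having 3314 to 4134 at an unadjusted p under 0.05. It was 399 with normexp, 444 with quantile scaling, 552 with series values, 562 with probe means and 667 with a trended spread. For post-mortem limma called 0 (4132 unadjusted), 229 with normexp, 14 with probe means, 20 with relapse aspirate 3 as the lone array and 0 to 431 when each array was left out, and 0 in the other settings (225 to 5229 unadjusted). Of the lists, 18 were called, 14 with quantile scaling, 22 with normexp, 0 with an estimated correlation and 30 with the added ones, 2 of them fixed lists at relapse that pass only then (0.0402). Targets 2-fold apart fell to 763 from 2102 for MalcolmX with normexp, to 306 from 1122 for remission against failed chemotherapy and to 580 from 2018 for the second aspirate against the first biopsy. The offset of normexp shrinks differences of dim probes by construction, the filters change the number of targets tested, and leaving out arrays, single slides and lone arrays change the samples. For the other changes the cause was not tested. Counting each named gene once per alternative, 62 values of the biopsies against skin and 134 of relapse lost their call and 22 and 27 gained one, while 447 and 294 kept direction and side of the threshold. A list of anaphase promoting complex substrates, fixed with its own alternatives, gave no value under any of them, since 2 of 35 members were named. Signal over background limits the dim group of each fold written as a lower bound, and 66.8% to 75.9% of probes were well above background on an array.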

Other observations

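All tests named in this part were chosen after the results were seen. Gland genes were among the brightest in the first biopsy of Rosco and in the second resistant aspirate. KLK1, a glandular kallikrein, stood at 7.29 and 7.23 there and at most at 0.61 on any other array, and TFF3, a mucosal peptide secreted with mucus, at 7.74 and 7.59 against −5.67 or lower. LTB, a lymphotoxin of B and T cells, stood at −2.52 and −2.57 in these samples, close to the Rosco skin at −2.65, and at 4.14 or more in every other tumour sample. CD40 stood at −0.42 and −1.03 there, and the proliferation list at 0.38 and 0.08 against 1.00 or more in the other tumour samples. Of the 22 gland genes 8 were also well above background on all 3 other resistant biopsies and 2 belonged to another list.

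In the failed-chemotherapy and remission aspirates CD38, an ectoenzyme of plasma cells and activated lymphocytes, stood at 3.78 and 4.44 against at most 1.00 elsewhere, and IL2 at −1.12 and 0.08 against −4.84 or lower. The multidrug pump gene ABCB1 was highest in these aspirates (0.88 and 0.34) and at −1.75 or lower on every other array. CD8A stood at 3.21 and 2.90 in them, at −1.53 in the sensitive biopsy and at −3.04 or lower elsewhere. BIRC5 was at 1.32 and 0.69 in them against 2.89 to 3.00 in the relapse aspirates. The MalcolmX skin differed from the Rosco skin in MS4A1, at 0.84 against −8.03, and in the Skeletal muscle markers, at 4.49 against −0.83. Lists of other blood cells differed less and in both directions. Macrophages were at −1.12 against −0.43, neutrophils at −3.33 against −2.18, erythroid genes at −3.51 against −4.12, and T and NK cells at −4.77 against −5.23.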
